A study of Homo sapiens with 4 samples.

How the data were processed

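Total RNA was taken from HCT116 cells with TRIzol and sequenced on an Illumina HiSeq instrument by a service provider, per the labels' protocols. The 4 groups of 1 library each were assigned from the cell type given in the labels: CBFB overexpression, vector control, CBFB shRNA and shRNA control, all by lentivirus. The submitters' processing notes name CASAVA, TopHat and Cufflinks, without versions, and the genome build mm9. That build is of the mouse, whereas 60675 of the 61302 entries of the tables have human Ensembl gene IDs, so it cannot be the build behind these values. The read counter, the annotation release and the strand setting are not given in the sources used here. The remaining 627 entries have IDs outside Ensembl and took 0.539% to 0.792% of each library's counts.

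The authors deposited raw counts per gene, whole numbers that are not normalized. The deposited FPKM values are the same counts divided by gene length and by the column total of the count table: in all 10792 genes with at least 100 counts in every library, count and FPKM implied the same length in all 4 libraries, within a relative tolerance of 1e-04. The count table was used for every main result and the FPKM table as an alternative. Gene symbols were matched by Ensembl ID for 56558 entries, and positions came from GENCODE release 29 on GRCh38, which held 57055 of the IDs. These positions describe the genes, not the authors' alignment.

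Genes needed at least 1 CPM in at least 1 of the 4 libraries, which kept 15892. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.007, 0.978, 1.011 and 1.004 for the overexpression, vector control, CBFB shRNA and shRNA control libraries. Each log2 ratio is a ratio of scaled CPM with a prior count of 1. Beside it stands the exact (Clopper-Pearson) 95% interval of the ratio of the 2 counts without the prior, which covers counting error only. PCR reads without molecular identifiers are not independent molecules, and variation between cultures is not in these intervals. A count of 0 was taken to allow 3 counts. A gene was called different where its log2 ratio reached the threshold, 2-fold in a single comparison or 1.5-fold where both comparisons were joined, and its interval excluded 0. No p-value was computed from a single pair of libraries.

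The test over both vector systems was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on the counts with the vector system and the CBFB level as terms, at a Benjamini-Hochberg adjusted p of 0.05. It has 1 residual degree of freedom, so the spread is the disagreement between systems, borrowed across genes, and no condition is replicated. The samples are not stated to come from separate cultures, and p-values then measure only the spread between these libraries.

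A set of 32 gene lists, the rule for named genes, the tests, the thresholds and the alternatives not said otherwise were fixed before the data were examined. The lists covered the CBF complex, the study's targets, RUNX2 targets, cell state, stress, metabolism, signalling, differentiation, histones and markers of other cell types. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, for the 31 lists with at least 3 measured genes. This describes these libraries and is not a test. Of the 31 lists, 16 lay outside the middle 95% with overexpression, 12 with shRNA and 18 between the controls. For lists of randomly drawn genes 1.55 would be outside in each, which is not a chance rate for lists of related genes. The study's targets, chosen on these samples, count in each, and with shRNA so does the CBF complex list, which holds CBFB. Lists share some genes: NIBAN1 is both a study target and an integrated stress response gene. The results of 1 of the 32 lists are not described or drawn, although it stays in these counts.

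Named genes followed a rule: 7 genes in every case (CBFB, RUNX1, RUNX2, RUNX3, SPP1, NIBAN1 and UPP1), the 10 highest and 10 lowest ratios per comparison with at least 50 counts in the higher library and a symbol, skipping clones and pseudogenes, the 10 leading genes in each opposite direction, up to 4 leading members per list and the 10 genes of lowest p. The files give no gene type, so an antisense gene could be named. Members of the groups with smaller ratios, and genes that followed CBFB against both controls, were chosen after their values were seen. Genes on chromosome Y and XIST were kept in the fits and counts and are not named.

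The calls were tested on simulated data drawn from the mean of the libraries and their sizes, over 15892 genes. Pairs were simulated with counting error only, so variation between cultures is not in these figures, and 100 genes were changed at each fold. For the overexpression comparison, 96% of 3-fold and 98% of 4-fold changes were called, with 42 false calls. For the shRNA comparison these were 96% and 99%, with 52 false calls. For the test over both systems, a fixed spread beyond counting error was simulated. Every library had the same baseline, without a difference between the systems or an outlying control. There the test called 78% of 2-fold and 100% of 4-fold changes, with 8 false calls. These figures do not measure false calls in the deposited libraries, whose controls differed widely.

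Alternatives, one at a time, were DESeq2 1.42.0 size factors, plain totals, no filter, at least 5 CPM, prior counts of 0.25 and 5, log2 of FPKM plus 1, thinning all libraries to the smallest total, other fold thresholds, DESeq2's Wald test, limma 3.58.1 with voom, and designs without the block or with a trend over CBFB level. Exchanged controls, further conditions on the joined sets, a robust prior, TMM factors before the filter and a fit without chromosome Y genes were added after seeing the data. Figures were drawn with matplotlib, and their Poisson intervals computed with scipy.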

Results

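The study measured mRNA in HCT116 cells, an established human colorectal carcinoma line, after the level of CBFB had been raised or lowered with lentiviral vectors. CBFB encodes core-binding factor beta, the partner that stabilises DNA binding by the RUNX transcription factors. There were 4 groups with 1 RNA-seq library each: cells carrying a CBFB overexpression vector, their vector control, cells carrying an shRNA against CBFB, and their shRNA control. The count table summed to 23103715 counts in the overexpression library, 20376696 in the vector control, 20567790 in the CBFB shRNA library and 19803344 in the shRNA control. At least 1 count was found for 28588, 27490, 28883 and 28949 genes, in the same order. With 1 library per group no difference has a replicate check, so a pair of libraries is compared here, not a pair of conditions. Each log2 ratio is given with a 95% interval of the ratio of its 2 counts, which covers counting error only. A count of 0 allowed up to 0.130 CPM in the overexpression library, 0.147 in the vector control, 0.146 in the CBFB shRNA library and 0.152 in the shRNA control.

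CBFB itself followed the labels. The gene (ENSG00000067955, chromosome 16, 67029116 to 67101058 on GRCh38 in GENCODE release 29) stood at 423 CPM in the overexpression library and 130 CPM in its vector control, a log2 ratio of 1.71 (1.64 to 1.77), or 3.26-fold. It stood at 40.7 CPM with CBFB shRNA and 108 CPM in the shRNA control, a log2 ratio of -1.41 (-1.52 to -1.29). The controls differed in CBFB by a log2 ratio of -0.26 (-0.35 to -0.18, shRNA control over vector control), and the overexpression library exceeded the CBFB shRNA library by 3.37. Gene counts do not separate the introduced copy from the cell's own transcript.

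Among the RUNX partners, RUNX1 was higher with CBFB overexpression, by a log2 ratio of 0.82 (0.72 to 0.91), and lower with CBFB shRNA, by -0.63 (-0.73 to -0.53). Against the other pair's control these ratios were 0.25 and -0.06. RUNX2, the partner named in the study's title, was scarce: 6.62 CPM with overexpression, 17.7 in the vector control, 5.53 with CBFB shRNA and 6.84 in the shRNA control. Its log2 ratio was -1.41 (-1.70 to -1.14) with overexpression and -0.30 (-0.68 to 0.06) with shRNA, and the shRNA control lay -1.37 from the vector control. Against the other pair's control RUNX2 had -0.05 with overexpression and -1.67 with shRNA. RUNX3 gave -0.24 (-0.37 to -0.11) and 0.14 (0.00 to 0.28). The CBF complex list, made of CBFB and the 3 RUNX genes, had 2 of 4 members at least 1.5-fold higher and 1 lower with overexpression, and 2 lower with shRNA.

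Of the 3 genes known as targets from the study itself, NIBAN1 (FAM129A) and UPP1, the uridine phosphorylase of pyrimidine salvage, were higher with CBFB overexpression and lower with CBFB shRNA. These genes were chosen by the study on these samples, so their direction is not independent evidence. NIBAN1 had a log2 ratio of 2.37 (2.19 to 2.55) with overexpression and -1.58 (-1.71 to -1.46) with shRNA. UPP1 had 1.35 (1.22 to 1.49) and -1.28 (-1.37 to -1.20). SPP1, which encodes the secreted phosphoprotein osteopontin, had between 15 and 24 counts per library, and its log2 ratios of -0.40 (-1.33 to 0.49) and -0.06 (-1.20 to 1.07) were not distinguishable from 0 at this depth. Both NIBAN1 and UPP1 also differed between the control libraries, by log2 ratios of 2.80 (2.63 to 2.99) and 2.55 (2.43 to 2.68), more than in either CBFB comparison. Overexpression and shRNA compared directly gave 1.15 (1.02 to 1.27) for NIBAN1 and 0.08 (-0.02 to 0.18) for UPP1. Against the other pair's control both genes turned direction, to -0.44 and -1.20 with overexpression and to 1.22 and 1.27 with shRNA.

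**Figure D1:**
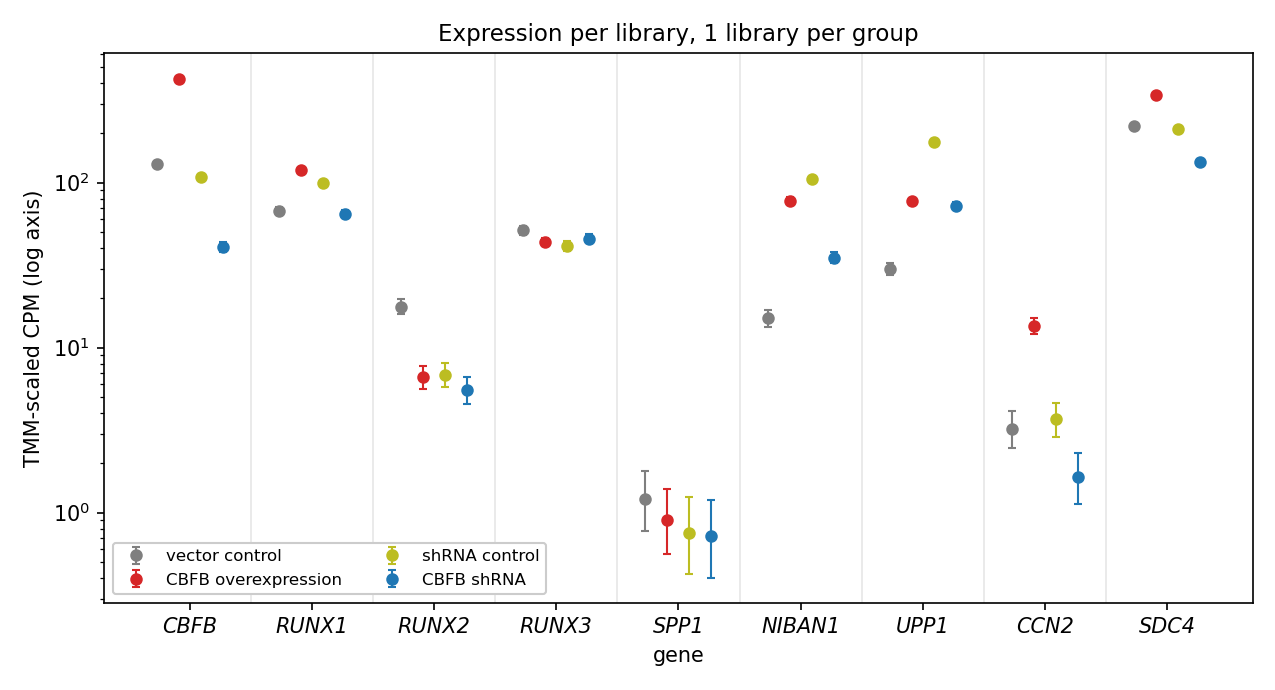
TMM-scaled CPM (log axis) of 9 genes in each of the 4 libraries, with exact 95% Poisson intervals as bars. CBFB runs from 423 CPM with overexpression to 40.7 CPM with shRNA with both controls between them, whereas NIBAN1 and UPP1 are highest in the shRNA control, at 105 and 177 CPM.

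The comparison of CBFB overexpression with its vector control asks which transcripts differ when CBFB is raised. The genes with the highest ratios included IL32, a cytokine, at 504 counts against 34, with a log2 ratio of 3.63 (3.17 to 4.21), PRF1, which encodes perforin, at 3.23 (2.89 to 3.62), and the transmembrane mucin MUC13 at 3.22 (2.51 to 4.20). The glutathione-degrading enzyme CHAC1 had 3.16 (2.91 to 3.45), the bestrophin channel gene BEST1 had 3.55 (2.57 to 5.23) and the collagen VI chain COL6A3 had 3.04 (2.49 to 3.76). The other genes among the 10 highest were MAGEB1, SELENOP, CCDC102B and RGMB-AS1, the last an antisense gene whose reads are not separated from its partner's here, since the strand setting is not given in the sources used. The lowest ratio belonged to PROM1, the CD133 glycoprotein, with 17 counts against 595 and a log2 ratio of -5.26 (-6.14 to -4.66). HAS3, a hyaluronan synthase, had -3.21 (-3.37 to -3.05), the transcription factor NFIB had -3.23 (-3.79 to -2.79) and peroxidasin, PXDN, had -3.31 (-3.68 to -2.99). The rest of the 10 lowest were STXBP6, MYPN, GALNT14, SPOCK1, DPEP1 and ANXA10. Against the shRNA control PROM1 had -5.48, NFIB -3.74, PXDN -3.23 and ANXA10 -3.09, while MUC13 had 3.95, MAGEB1 3.15 and IL32 3.06. Other genes lost or turned their difference there, with SPOCK1 at 0.08, BEST1 at -0.65, CHAC1 at 0.41, RGMB-AS1 at 0.62 and COL6A3 at 0.78.

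Integrated stress response genes, the targets of ATF4 and CHOP, were higher with overexpression as a group. Of 19 measured, 16 were at least 1.5-fold higher, 1 (ATF5) was lower and 2 were not different by that criterion. Asparagine synthetase, ASNS, had a log2 ratio of 2.71 (2.64 to 2.77), the mTORC1 inhibitor gene DDIT4 had 2.85 (2.66 to 3.05), the cystine transporter gene SLC7A11 had 2.68 (2.60 to 2.77) and the serine synthesis enzyme PHGDH had 2.19 (2.11 to 2.28). The list's median was 1.26, above all 10000 random lists of matched expression. The same list had a median of 1.19 between the controls, the shRNA control being at least 1.5-fold higher than the vector control in 15 of the 19 genes.

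Hypoxia and glycolysis genes had a median of 0.41 with overexpression (percentile 100), with 9 of 23 at least 1.5-fold higher, 1 lower and 13 neither. The glucose transporter gene SLC2A3 had 2.99 (2.83 to 3.15) and NDRG1 had 1.48 (1.41 to 1.55). Epithelial genes had a median of 0.38 (percentile 100), with 8 of 18 higher, none lower and 10 neither. E-cadherin, CDH1, had 1.12 (1.01 to 1.23) and claudin 7, CLDN7, had 1.21 (1.09 to 1.34). Heat shock chaperones had a median of -0.65 (percentile 0), with 8 of 14 lower and 6 neither. The constitutive chaperone HSPA8 had -1.02, with 34995 counts against 60809, and HSP90AB1 had -0.70 (-0.71 to -0.69). Ribosome biogenesis and MYC targets had a median of -0.48 (percentile 0), with 5 of 21 lower, among them ODC1 at -0.68 (-0.72 to -0.64), while MYC itself was at -0.01 (-0.05 to 0.04). Between the controls the medians of these 4 lists were 1.46, 0.59, -1.09 and -0.62, each farther from 0 than with overexpression and of the same sign.

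Proliferation genes had a median of -0.27 with overexpression (percentile 0.41), with 2 of 26 lower, FOXM1 at -0.77 (-0.85 to -0.69) and PLK1 at -0.61 (-0.68 to -0.54). Widely described RUNX2 targets, a list chosen in advance, had a median of 0.04 over 9 measured genes (percentile 70.0), with VEGFA at 1.10, with 2812 counts against 1121, and SNAI2 at -1.96 (-2.84 to -1.26). Mesenchymal genes had a median of 0.04 (percentile 56.1), with 2 of 9 higher and 1 lower. Vimentin, VIM, had 1.88 (1.41 to 2.43). Between the controls these 3 lists had medians of -0.67, 0.10 and 0.42, in the same order.

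In all, 1197 of 15892 genes were at least 2-fold different between the overexpression library and its vector control, 940 higher and 257 lower, with intervals that excluded no difference. Against the shRNA control the direction turned: 317 genes were higher and 667 lower. A filter at 5 CPM left 540 genes, and the FPKM table gave 425.

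The comparison of CBFB shRNA with its control asks which transcripts differ when CBFB is lowered. The lowest ratios belonged to LCN2, which encodes the siderophore-binding lipocalin 2, at 9 counts against 99 and a log2 ratio of -3.39 (-4.70 to -2.54), to SPX, the peptide hormone spexin, at -3.18 (-4.10 to -2.51), and to BEST1 at -2.74 (-3.58 to -2.10). The galactosyltransferase gene B3GALT5 had -2.56 (-2.87 to -2.28), with 112 counts against 636, and was at 672 and 590 counts in the overexpression library and its control. The other genes among the 10 lowest were COL6A3, HKDC1, LURAP1L, IL20RB, ARRDC4 and SPRR2D, the last from a family of closely similar genes whose shared reads make its value uncertain. The highest ratio belonged to SCG2, a secretogranin, with 1131 counts against 357 and a log2 ratio of 1.60 (1.43 to 1.77). ANGPT2, a ligand of the TIE2 receptor, had 1.41 (1.01 to 1.85), the cell cycle phosphatase CDC25A had 1.15 (0.98 to 1.32), the growth factor BMP4 had 1.11, with 1884 counts against 832, and AGPAT5 had 1.05 (0.98 to 1.12). PWWP3B, TMSB15A, LCP1, SYP and UTS2 completed the 10 highest. Against the vector control B3GALT5 had -2.45 and SCG2 2.01, whereas LCN2 had 0.27, SPX 0.86, BEST1 1.46, CDC25A -0.40 and BMP4 -0.31, each of the opposite sign.

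With CBFB shRNA the integrated stress response list had a median of -0.53 (percentile 0), with 8 of 19 genes at least 1.5-fold lower, none higher and 11 neither. DDIT3, which encodes CHOP, had -1.34 (-1.66 to -1.05) and ASNS had -1.04, with 8550 counts against 16798. All 23 hypoxia and glycolysis genes had ratios below 0, with a median of -0.29 (percentile 0), although only SLC2A3 passed 1.5-fold, at -0.72 (-0.87 to -0.57). Epithelial genes had a median of -0.20 (percentile 0.050), with 2 of 18 lower: the splicing regulator ESRP1 at -0.70 (-0.75 to -0.64) and ELF3 at -0.64 (-0.74 to -0.53). Heat shock chaperones had a median of 0.46 (percentile 100), with 3 of 14 higher, including HSPH1 at 0.66 (0.60 to 0.73). HSPA1B, at 0.77 (0.66 to 0.87), shares reads with its near-identical copy HSPA1A, which makes both uncertain. Proliferation genes had a median of 0.13 (percentile 98.4), with 1 of 26 higher. Ribosome biogenesis genes had 0.17 (percentile 99.6), with none of 21 past 1.5-fold. RUNX2 targets had a median of 0.02 (percentile 50.1), with none of 9 past 1.5-fold, and mesenchymal genes had 0.06 (percentile 69.6), with none of 9. The control medians given for these lists apply here as well: in the stress response, hypoxia, epithelial and heat shock lists the shRNA control departed from the vector control in the direction in which it departed from the CBFB shRNA library. Between the overexpression and shRNA libraries directly, the stress response list had a median of 0.64 (percentile 100), heat shock 0.01 (percentile 45.5), epithelial genes -0.04 (percentile 17.3) and ribosome biogenesis 0.11 (percentile 94.6). Hypoxia and glycolysis had -0.79 (percentile 0) and proliferation 0.23 (percentile 99.99), both opposite in sign to the overexpression comparison.

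A total of 387 genes were at least 2-fold different between CBFB shRNA and its control, 85 higher and 302 lower. Against the vector control the number was 1425, 1105 higher and 320 lower, and a filter at 5 CPM left 77.

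The control libraries, in which CBFB had not been altered by design, served as background. They differed at least 2-fold in 1934 genes, 1547 higher in the shRNA control and 387 lower, more than in either CBFB comparison. Of the hypoxia genes, 17 of 23 were at least 1.5-fold higher in the shRNA control, with NDRG1 at a log2 ratio of 3.16, ALDOC at 3.40 and PDK1 at 2.34. Of the heat shock chaperones, 12 of 14 were lower there, HSPH1 at -1.89. The vector control was also the library that stood farthest from the rest. It differed at least 2-fold from each of the other 3 libraries in 456 genes, 402 of them lower in it, while the number was 187 for the overexpression library, 84 for the shRNA control and 45 for the CBFB shRNA library.

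The study's design asked which genes differed in both comparisons. Genes higher with overexpression and lower with shRNA by at least 1.5-fold numbered 279, where independent lists would share 99.3. BEST1, SPX, COL6A3, LURAP1L, IL20RB, NIBAN1, LAMP3, RBCK1, SYNE3 and CBFB had the largest ratios in both. RBCK1, a component of the linear ubiquitin chain assembly complex, had log2 ratios of 1.72 (1.63 to 1.82) and -1.43, the latter from 2462 counts against 6355, and SYNE3, a nesprin of the nuclear envelope, had 2.86 (2.64 to 3.11) and -1.41 (-1.63 to -1.20). The reverse set held 55 genes, where 17.6 would be shared, led by PWWP3B, SH2D2A, IL6R, PDE4B, GAL, HSPA1B, DUSP2, ADAM19, SH3RF2 and DPEP1. PDE4B, a cyclic AMP phosphodiesterase, had -1.60 (-1.69 to -1.51) and 0.80 (0.70 to 0.89), and the receptor gene IL6R had -1.23 (-1.43 to -1.04) and 0.86 (0.66 to 1.06). Genes moving the same way in both by at least 1.5-fold were not in excess at that threshold. Of them, 38 were higher where 43.0 would be shared and 33 lower where 40.8 would be. At 2-fold, 25 genes moved the same way and 90 opposite ways. At that threshold 940 and 85 genes were higher, and 257 and 302 lower, with overexpression and shRNA. By the same rule independent lists of these sizes would share fewer than 25 same-way genes. Same-way genes were therefore in excess at 2-fold, unlike at 1.5-fold. Across the 15892 genes, which are not independent replicates, the log2 ratios of the 2 comparisons had a Pearson r of -0.25 and a Spearman rho of -0.27. Without the filter on low counts, Pearson r was -0.058.

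Most of these genes also differed between the controls in the same direction as with overexpression: 249 of the 279 and 42 of the 55. Between the overexpression and shRNA libraries directly, 144 of the 279 and 29 of the 55 differed by at least 1.5-fold in the matching direction, and 7 of the 279 in the other. With the controls exchanged between the comparisons, the sets held 240 and 680 genes, so the balance of directions turned. Genes that followed CBFB against both controls were 13, CBFB itself included, and 5, and how many would do so by chance was not computed. Among them, chosen after their values were seen, were CCN2, which encodes connective tissue growth factor, with log2 ratios of 2.06 (1.68 to 2.48) and -1.14 (-1.80 to -0.56), the syndecan SDC4 with 0.62 (0.56 to 0.67) and -0.66 (-0.73 to -0.59), and SUSD2 with 1.11 (0.79 to 1.46) and -1.32 (-1.78 to -0.90). In the other direction were the metalloproteinase gene ADAM19, with -1.29 (-1.44 to -1.15) and 0.74 (0.67 to 0.81), SCG2, and RNF141 with -0.79 (-0.87 to -0.72) and 0.73 (0.67 to 0.79). Between the controls the log2 ratios were 0.19 for CCN2, -0.06 for SDC4, 0.51 for SUSD2, 1.07 for ADAM19, 0.41 for SCG2 and 0.02 for RNF141.

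**Figure D2:**
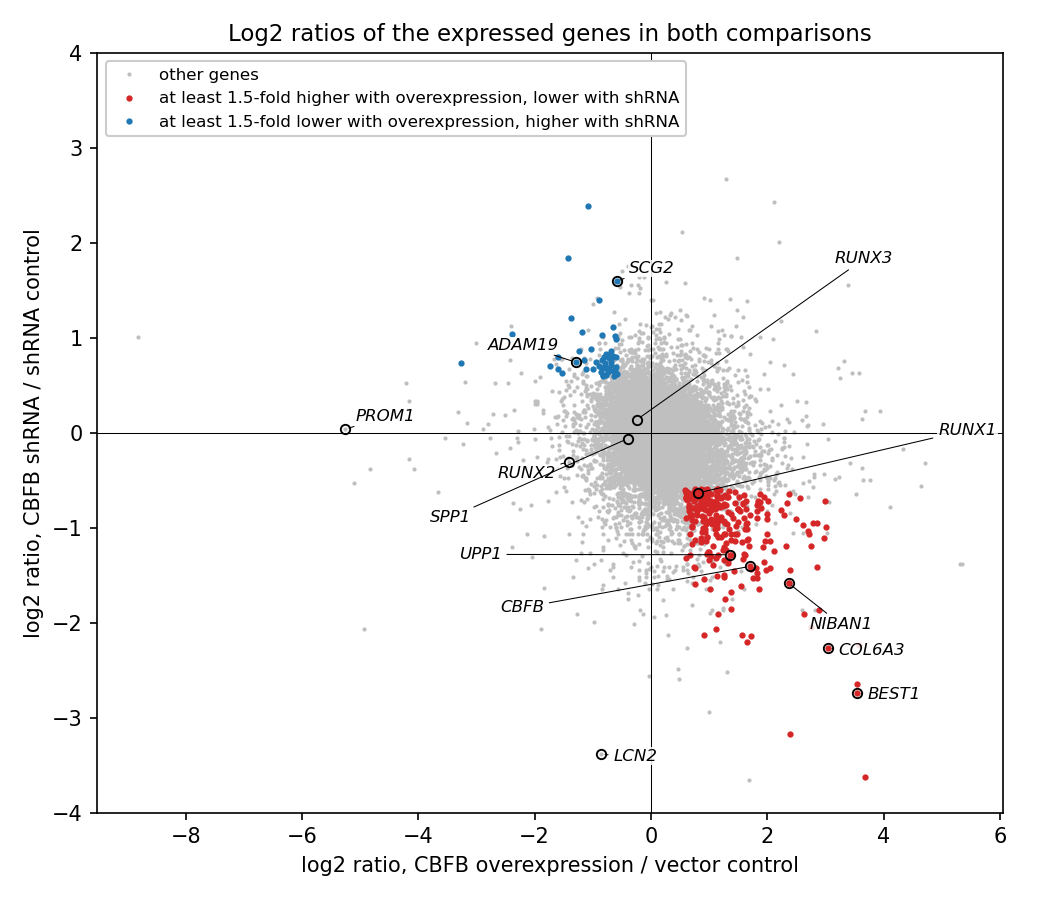
Log2 ratio with CBFB overexpression (x axis) against log2 ratio with CBFB shRNA (y axis) for 15882 genes, 1 point each. Red marks the 279 genes at least 1.5-fold higher with overexpression and lower with shRNA, blue marks 53 of the reverse set, and circles mark named genes such as NIBAN1 at 2.37 and -1.58.

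The main test across genes takes the vector systems as a pair of observations of higher against lower CBFB, each within its own system. The overexpression library and the shRNA control were the CBFB-high libraries, and the vector control and CBFB shRNA library the CBFB-low ones, with the system as a block and 1 residual degree of freedom. These names hold within a system only, since CBFB was at 108 CPM in the shRNA control and 130 CPM in the vector control. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 274 genes rose and 84 fell with CBFB in this sense. The tested difference gives shRNA control over vector control the same weight as overexpression over CBFB shRNA. A difference between the controls alone can therefore give a call. UPP1 stood at 76.9 CPM with overexpression and 72.6 with CBFB shRNA, but at 30.1 in the vector control and 177 in the shRNA control. A trend over the order of CBFB levels, with both controls in the middle, passed no gene in edgeR, with 478 at an unadjusted p under 0.05, and gave NIBAN1 and UPP1 trends of 0.57 and 0.04 on the log2 scale (adjusted p = 0.9998). CBFB itself, with a trend of 1.69, did not pass there either (adjusted p = 0.12), so a call lost in the trend says little. NIBAN1 rose by a log2 fold change of 1.97 (adjusted p = 6.4e-08) and CBFB by 1.56 (adjusted p = 2.3e-07). RBCK1, the microtubule protein MAP1B, SYNE3, LURAP1L, ARRDC4, UPP1 and ASNS were also among the 10 genes of lowest p. First in that order was ENSG00000259001, annotated as an antisense gene, with 814 counts in the vector control and at most 1 elsewhere. That p rests on the vector control, since CBFB shRNA and its control had 1 and 0 counts. A low p in this test thus does not require a difference in both systems. ENSG00000259001 overlaps PARP2 and RPPH1, and without a known strand setting its reads are not assigned to a strand here. RUNX1 rose (adjusted p = 0.0085), a call lost with DESeq2 in the same design (adjusted p = 0.063) and in the trend (0.9998) and kept with limma-voom (0.0039), while RUNX2 (0.37), RUNX3 (0.66) and SPP1 (0.91) did not pass. CCN2 and SDC4 did not pass with DESeq2 in that design (adjusted p = 0.079 and 0.085) or in the trend (0.9998 for both). With limma-voom both passed (0.00049 and 0.0072).

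The list counts of this test also include the difference between the controls, so they do not single out CBFB. By this test 15 of 19 integrated stress response genes rose over all genes tested and 17 passed when adjusted over the list alone. Heat shock chaperones fell in 7 of 14, and 10 passed adjusted over the list alone. The counts over all genes and adjusted over the list alone were 4 and 8 of 23 for hypoxia and glycolysis, 4 and 7 of 18 for epithelial genes, 0 and 5 of 21 for ribosome biogenesis, 1 and 1 of 26 for proliferation, 1 and 1 of 9 for RUNX2 targets and 0 and 3 of 9 for mesenchymal genes. For the CBF complex they were 2 and 2 of 4, and for the study's targets 2 and 2 of 3, the latter not independent evidence. The vector system itself separated 1178 genes. Altered against unaltered CBFB separated 1, but in that fit the difference by CBFB level became the spread. That low number therefore cannot show that such an effect is absent. The number of genes varied widely between settings: DESeq2's Wald test called 80 genes in the same design and limma-voom 425, a robust prior gave 211, and TMM factors taken before the filter gave 77. Without the system block no gene passed in edgeR, with 554 at an unadjusted p under 0.05.

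**Figure D3:**
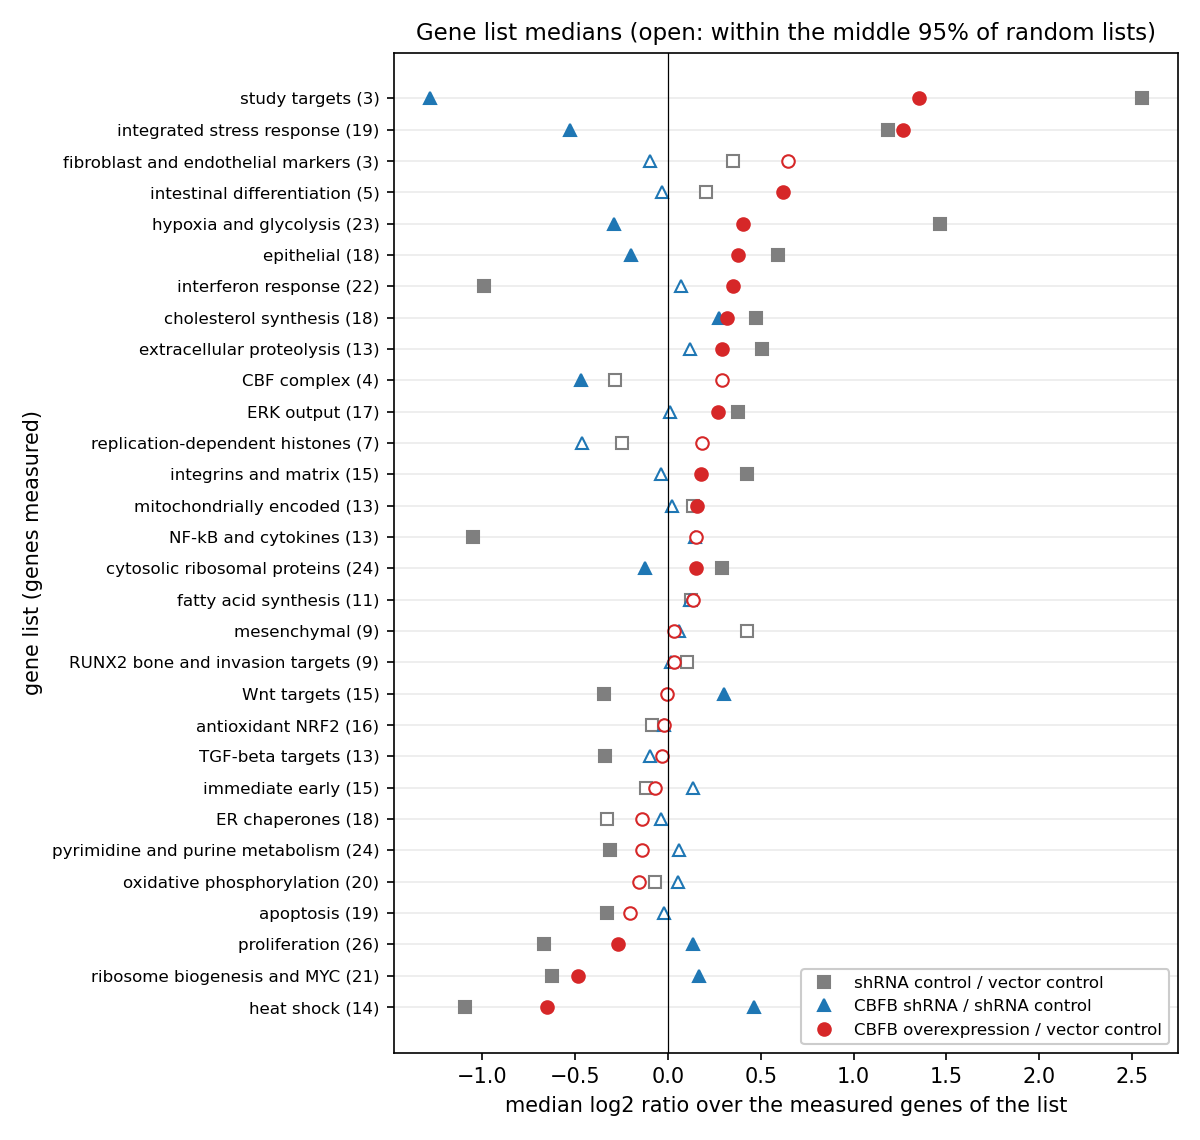
Median log2 ratio of the gene lists described (x axis, genes measured in brackets) in the overexpression comparison (red circles), the shRNA comparison (blue triangles) and between the controls (grey squares), with filled symbols outside the middle 95% of matched random lists. The integrated stress response stands at 1.26, -0.53 and 1.19, and heat shock at -0.65, 0.46 and -1.09.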

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

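The test for genes at least 2-fold higher in both comparisons was chosen only after the ratios were seen. The overexpression and shRNA comparisons had opposite directions in most genes that differed in both, but 25 of all genes tested moved the same way by at least 2-fold in both. Of these, 3 had a gene symbol and at least 50 counts in the higher library of both comparisons, all higher in both. Independent lists of the sizes called at 2-fold would share fewer than 25 same-way genes. ANGPT2 had a log2 ratio of 1.36 with overexpression and 1.41 with shRNA, UTS2 had 1.16 and 1.08, and TMSB15A had 1.04 and 1.12. Against the vector control the shRNA ratios were 0.35, 0.82 and 0.95, and from log2 of FPKM plus 1 they were 0.91, 0.75 and 0.98, all under 2-fold. With a prior count of 5 UTS2 had 0.97 with shRNA. TMSB15A has a close paralog, TMSB15B, and reads shared between them make its value uncertain. With 1 library per group the difference between the comparisons was not tested.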

How the results depend on the processing

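The comparisons against the other pair's control, the further conditions on genes moving opposite ways, the TMM factors before the filter, the robust prior and the fit without chromosome Y genes were chosen after seeing the data. No paired analysis was possible between replicates of a group because each group has 1 library, although the test over both systems blocks on the vector system. Under DESeq2 size factors all 81 named-gene ratios stayed within their counting intervals, as they did under plain totals and a prior count of 5. With log2 of FPKM plus 1, 34 of 81 left their intervals. The FPKM values are the same counts over length and column totals, and plain totals moved none. The 1 added to FPKM, which shrinks ratios of genes with low FPKM, therefore accounts for these moves. List medians have no interval here and were called moved from a fixed shift of 0.1 on the log2 scale. Under DESeq2 size factors all 62 list medians shifted by less. At least 5 CPM left 540 genes 2-fold different with overexpression, 77 with shRNA, 934 between the controls and 202 moving opposite ways. From log2 of FPKM plus 1, used without an interval, the numbers were 425, 79, 821 and 165. Plain totals gave 1278, 381, 1992 and 335. A 1.5-fold threshold gave 2891, 1103 and 4405, and without a filter the shRNA comparison gave 735. The filters changed the number of genes tested and the threshold the size required, while log2 of FPKM plus 1 kept the 15892 genes. Genes moving opposite ways numbered 90 at 2-fold, 1494 at 1.2-fold, 173 when also different directly, 18 against both controls and 920 (240 and 680) with the controls exchanged. CBFB shRNA against the vector control gave 1425 genes. The correlation across genes was -0.058 without a filter. The test over both systems called 80 genes by DESeq2's Wald test, 77 with TMM factors before the filter, 211 with a robust prior and 568 at an adjusted p of 0.1. In edgeR it called 0 without the block, with 554 at an unadjusted p under 0.05, and 0 for a trend over CBFB level, with 478. Both numbers are below the share of 0.05 to be found by chance among 15892 genes. Without chromosome Y genes it called 279. Against the other pair's control RUNX1 moved to 0.25 and -0.06 and RUNX2 to -0.05 and -1.67, and other log2 ratios turned sign: RUNX3 0.073 with overexpression and -0.17 with shRNA, NIBAN1 -0.44 and 1.22, UPP1 -1.20 and 1.27. Of 67 further named ratios, 29 changed sign there. At least 5 CPM moved the medians of the study's targets to 1.89 and -1.45, of histones to 0.30 and -0.59, with overexpression and shRNA, of RUNX2 targets to 0.25, TGF-beta targets to 0.10, hypoxia to 0.29 and NRF2 to 0.084 with overexpression, and of Wnt targets to 0.15, immediate early genes to 0.011 and NF-kB genes to 0.26 with shRNA. Log2 of FPKM plus 1 moved the stress response to 1.14 and intestinal genes to 0.46 with overexpression, and histones to -0.21 with shRNA. Apart from the filters, the thresholds and the 1 added to FPKM, the cause was not tested. Depth limits SPP1, at most 24 counts, and genes near the floor of 3 counts.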

Other observations

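The tests of CBFB mRNA level alone, of the stress state of the cultures and of the H1 promoter were chosen only after the result was seen. Some interferon genes differed widely between the vector systems. IFIT1, an antiviral RNA-binding protein, had 1628 counts with overexpression and 1187 in the vector control, against 136 with CBFB shRNA and 99 in the shRNA control, and IFIT2 had 1482 and 1163 against 47 and 40. The interferon list had a median log2 ratio of -0.99 between the controls (13 of 22 genes at least 1.5-fold lower in the shRNA control and 5 higher, percentile 0), 0.35 with overexpression (7 of 22 genes at least 1.5-fold higher, percentile 99.2) and 0.07 with shRNA (2 higher, 1 lower, percentile 87.0). NF-kB and cytokine genes had -1.05 between the controls, 0.15 with overexpression (3 of 13 higher) and 0.14 with shRNA (1 lower). In that list ICAM1, an adhesion receptor for leukocytes, was higher with overexpression by 2.41 (2.08 to 2.79). By the edgeR test over both systems 1 and 2 genes of these lists passed over all genes, and 1 and 2 adjusted over the list alone. Cholesterol synthesis genes had positive medians in both CBFB comparisons although most members did not reach 1.5-fold: 0.32 (4 of 18 higher, percentile 99.99) and 0.28 (1 higher, percentile 100), and 0.48 between the controls, with none passing the test on either adjustment. Changes of the same sign in both comparisons offset each other in that test, so it cannot speak to this pattern. FDFT1, the squalene synthase, had 0.61 (0.53 to 0.70) and 0.25 (0.18 to 0.32). Wnt targets had -0.01 (2 of 15 higher) and 0.30 (2 higher, percentile 99.99), and -0.34 between the controls, again with none passing. AXIN2, a feedback inhibitor of Wnt signalling, had -0.49 (-0.74 to -0.25) and 0.98 (0.62 to 1.36).

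Other lists are given with their medians for overexpression, shRNA and between the controls. ER chaperones had -0.14, -0.04 and -0.33, with 4 of 18 higher and 2 lower with overexpression and 3 lower with shRNA, among them HYOU1 at -1.37 (-1.43 to -1.31) and HSPA5 (BiP) at -0.85 (-0.88 to -0.82). TGF-beta targets had -0.03, -0.10 and -0.34, with 2 of 13 higher and 2 lower, then 1 higher and 3 lower. Extracellular proteolysis had 0.29, 0.12 and 0.51 (2 of 13 higher, then 1 lower), integrins and matrix 0.18, -0.04 and 0.42 (4 of 15 higher, then 2 lower) and ERK output 0.27, 0.01 and 0.38 (4 of 17 higher, then 1 higher and 1 lower). Immediate early genes had -0.07, 0.13 and -0.12 (1 of 15 higher and 1 lower, then 4 higher and 1 lower), apoptosis genes -0.20, -0.02 and -0.33 (1 of 19 higher and 2 lower, then 1 and 1) and NRF2 targets -0.02, -0.02 and -0.08 (2 of 16 higher and 3 lower, then none). Fatty acid synthesis had 0.13, 0.12 and 0.12 (3 of 11 higher, then none), and pyrimidine and purine metabolism -0.14, 0.06 and -0.32 (3 of 24 higher, then 1 lower). Ribosomal proteins had 0.15, -0.12 and 0.29 with none of 24 past 1.5-fold in either CBFB comparison. Oxidative phosphorylation had -0.16, 0.05 and -0.07 (1 of 20 lower, then none) and mitochondrially encoded genes 0.16, 0.02 and 0.13 (none of 13, then 1 higher). Histones had 0.18, -0.46 and -0.25 (none of 7, then 2 lower) and intestinal differentiation 0.62, -0.03 and 0.20 (3 of 5 higher, among them HNF4A at 1.66 (1.43 to 1.90), then 1 lower). Of fibroblast and endothelial markers 3 were measured, with 0.65, -0.10 and 0.35 (2 higher, then none), and of leukocyte markers 2, CSF1R at 0.74 and 0.08 and ITGAM at -0.72 and 0.16, none past 1.5-fold beyond counting error. Over all genes and adjusted over the list alone, the test passed 2 and 7 ER chaperones, 4 and 5 TGF-beta targets, 2 and 4 integrin and matrix genes, 0 and 4 ERK genes, 2 and 4 apoptosis genes, 2 and 3 pyrimidine and purine genes and 1 and 2 NRF2 targets. It passed 1 and 1 in proteolysis and fatty acid synthesis, 0 and 1 in immediate early and intestinal genes, and none in ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones, fibroblast and endothelial or leukocyte markers.

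The vector control differed at least 2-fold from each of the other 3 libraries in 456 genes. After thinning to the smallest total it still did so in 441 genes, the next library in 198, which argues against depth. Among protein-coding genes with a mean of at least 10 CPM the numbers were 104 and 34, which argues against a loss of scarce and non-coding transcripts as the whole cause. A smooth fit on GC content and length covered the 15360 genes with both. Of these, 1774 were at least 2-fold different between the controls before the fit and 1626 after it, not necessarily the same genes. This argues against that bias for the difference between the controls. The 456 genes were not counted separately after the fit. A difference in vector, culture or batch stays open and is confounded with the groups, and no biological explanation was tested.

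Of the 334 genes moving opposite ways, NIBAN1 and UPP1 among them, 87.1% differed at least 1.5-fold between the controls in the same direction as with overexpression. Between the controls the smaller log2 ratio of NIBAN1 and UPP1 was 2.55 and CBFB differed by -0.26, but with 1 library per control this bears on counting error only, so the level of CBFB mRNA alone stays open. In 50 simulations with equal controls the share was at most 37.6%, a bound set in advance as evidence against noise and selection, but the simulated spread was the fitted one and 1 library per group does not measure the spread between cultures, so noise and selection cannot be told apart from a real difference here. A stress state of the cultures may contribute, since the 18 other stress response genes had a median of 1.08 between the controls, 1.19 with overexpression and -0.51 with shRNA. Of the 334 genes, however, only 6 were on the stress response list, NIBAN1 included. An effect of CBFB on this response stays open as well.

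ENSG00000259001, an antisense gene on chromosome 14 (20343048 to 20343685) that contains RPPH1 and overlaps the start of PARP2, had 814 counts in the vector control and at most 1 in each other library, while RPPH1 itself had 0 in each library. Transcription from the neighbouring PARP2 is argued against, because PARP2 was at most 0.25 higher on the log2 scale in the vector control than in another library. RPPH1 lies beside the H1 promoter used in many shRNA vectors, so H1 promoter sequence in the control vector could give such reads, but the libraries with shRNA vectors, whose promoter the labels do not name, had 1 and 0 counts. The gene counts hold no read positions or vector sequence, so this cannot be told apart from expression of the locus, and no biological explanation was tested.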
